A study of Mus musculus with 8 samples.

How the data were processed

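Total liver RNA of 8 samples was measured, per the labels, in 3 ages and 2 genotypes, with 1 sample per group for wild type (5 days, 2 weeks, 1 month), 2 for the knockout at 5 days and at 1 month and 1 at 2 weeks. Per the labels' protocols, livers were flash frozen, RNA was extracted with TRIzol and purified on columns with DNase, and it was labelled with Cy3 for a one-colour array. Per the file headers, the arrays were of Agilent design 014868 with probe coordinates on mm9, scanned spots were quantified with Feature Extraction 10.7.3.1, and the values are processed signal intensity (with spatial and multiplicative detrending and surrogates for low values switched on and the separate background correction off) beside raw mean and local background intensity. The submitters' processing notes name Feature Extraction 10.7. The deposited matrix of the whole series holds log2 values of 41267 probes. Its sorted columns differ by at most 0.0081, as after quantile normalization by the authors with a tool not given in the sources used here, and its values have a Pearson r of 0.999 to 1.00 with the scanner values of the same array. All of its columns could be assigned to a sample (0 unmapped). Per the file headers, 4 arrays were on slide 1 (both 2-week arrays, the 5-day wild type and 5-day knockout replicate 2) and 4 on slide 2 (5-day knockout replicate 1 and the 1-month arrays), each slide scanned in its own run, so that slide is partly confounded with age.

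The values used were log2 of the processed signal, averaged over the spots of a probe without an outlier flag, minus the array's 75th percentile, with the mean of these percentiles added back. Each array had 45018 spots, 41174 distinct non-control probes and 0 saturated spots, and no values were imputed. Probes had to be well above background on at least 2 of 8 arrays, which 26224 did, and 82 probes were left out because every spot on some array had an outlier flag. Probe names were updated through RefSeq accessions or symbols for 33636 probes, and 7538 kept the name in the files. Where a gene had several probes (6137 genes) the one with the highest mean signal was taken, giving 17451 genes.

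Genotype over the 3 ages and age over both genotypes came from an additive fit with limma 3.58.1 in R 4.3.3 (4 residual and 2.31 prior degrees of freedom). The effects at single ages, their differences and age within knockouts came from a fit with 6 groups (2 residual and 2.19 prior degrees of freedom), in which the lone wild-type arrays and the 2-week knockout are assumed to vary like the knockout pairs. The p-values of the fit with 6 groups measure the spread within the knockout pairs alone, in which there is no pool. Those of the additive fit also count a change of the genotype effect with age as spread, and there pools stand beside single mice. All were adjusted by Benjamini-Hochberg with a threshold of 0.05. Knockout replicates of different ages with the same number did not pair (correlation of their deviations −0.000417). The 40 gene lists (1363 entries, 1258 measured), written from general knowledge of liver functions, liver cell types and tissues that can be carried over, were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and over the 3 ages with fry. With the estimated correlation the p-values rest on the residual degrees of freedom alone (4 or 2), so that a list could hardly pass. No list passed so in any comparison, age in the knockouts included. These p-values therefore cannot decide for or against a list. Lists at 2 weeks are given as medians. The knockout at 2 weeks against wild type had 1 array on each side, and no gene was to be named there before the data were examined. The tables were read with the data.table package, version 1.17.8, and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

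The samples, comparisons, tests, variations of the analysis, gene lists and the rule for named genes were chosen before the data were examined. By that rule Arid1a and Arid1b are always named. Over the 3 ages up to 12 genes per direction are named, those with the largest fold among genes past the test and on the same side in 5 of 5 knockouts, filled up with the smallest p among genes on the same side and at least 2-fold, given as not past. At 5 days, at 1 month and for their difference up to 6 per direction are named, and for age over both genotypes up to 6 per direction. Up to 4 members per list are named, those of smallest p over the 3 ages. Clones and predicted genes were left out. The rule asked for genes above background on at least 1 array of each side, but it was applied to the 2 genotypes over all ages and not to the sides of each comparison. Read by comparison it would have left out Wif1, Igf2, Bex1 and Grin3b at 1 month and Mup5 and Mup8 for age, each of which is given as a bound. The values of 3 genes that these rules would name are not reported here. Exceptions chosen after seeing the data are the genes named at 2 weeks and over the later ages, Afp, and the further ages at which some list members are given. The comparison over 2 weeks and 1 month was itself chosen after seeing the data.

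Variations chosen before the data were examined were normexp background with an offset of 50, quantile normalization, median centring, the deposited matrix, no filter or a filter of all 8 arrays, the mean of all probes, slide as a block, trended and robust variance, a 1.5-fold rule, and leaving out the 2-week pair or each array in turn. Normexp with the local backgrounds that carried an outlier flag set to the array's median, leaving out the 5-day arrays, and leaving out genes on X and Y were added after seeing the data. In the planned normexp these flagged backgrounds lifted the 5th percentile (log2) of the 2-week knockout to 10.1, of the 1-month wild type to 8.29 and of 1-month knockout replicate 2 to 9.79. After repair these were 6.00, 5.93 and 6.12. Where the planned and the repaired form differ, the difference comes from the flagged backgrounds. On simulated data with known changes of 1, 2 and 4 (log2) in 67 genes each, the fit over the 3 ages found 74.6%, 98.5% and 98.5% of them, and that at 1 month 1.49%, 80.6% and 94.0%. Other splits of the samples into groups of the same sizes were run for the results that compare at least 3 samples with 3.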

Results

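Liver RNA was measured on 8 one-colour arrays from C57BL/6 mice with a hepatocyte knockout of Arid1a and from wild-type mice. Knockout livers were taken from individual mice, 2 at 5 days, 1 at 2 weeks and 2 at 1 month. Each age had 1 wild-type array, a pool of 2 mice at 5 days and at 1 month and a single mouse at 2 weeks. Between 55.7% and 62.4% of the 41174 probes read well above background on an array, the 75th percentile of signal was 263 to 421, and 17451 genes were tested. The small number of arrays limits the precision of every value. All mice were labelled male, but at 5 days Xist, which is expressed from the inactive X chromosome, read 13.43 in knockout replicate 1 and 12.13 in the wild-type pool. The Y-linked gene Ddx3y was not above background in knockout replicate 1 (1.93) and read 9.42 in that pool. Knockout replicate 2 at 5 days had a male pattern (Xist 1.74, not above background, and Ddx3y 10.69), as had the 5 later arrays.

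Arid1a encodes the DNA-binding subunit of the BAF chromatin remodelling complex, and its probe read lower in 5 of 5 knockout arrays than in the wild type of the same age without passing the test. The only Arid1a probe, A_51_P118671 (NM_001080819, mm9 chromosome 4, 133235292 to 133235351), differed by −0.41 ± 0.12 on the log2 scale (SE, 5 knockout and 3 wild-type arrays, limma adjusted p = 0.223). The difference was −0.14 at 5 days, −0.58 at 2 weeks and −0.54 at 1 month. The difference between 1 month and 5 days was −0.40 (adjusted p = 0.629). The difference over the 3 ages was −0.42 with slide as a block, which for the genotype equals leaving out 5-day knockout replicate 1. It was −0.34 within slide 1 and −0.54 within slide 2. Slide 1 here holds 5-day knockout replicate 2 and the 2-week knockout, and slide 2 the 1-month knockouts, each against the wild type of its age. Values within the slides therefore differ by age as well and do not test the slide. The labels do not say which part of the gene was deleted, and whole liver holds cells other than hepatocytes. The paralogue Arid1b differed by −0.01 ± 0.10 (adjusted p = 0.982, lower in 3 of 5 knockouts) and lay on the other side of 0 under 5 of the alternatives.

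The comparison over the 3 ages asks which genes differed in knockout liver whatever the age. Sugct, a mitochondrial enzyme of glutarate metabolism, rose by 3.13 ± 0.17 (log2, SE), Cdhr2, a protocadherin of brush borders, by 3.16 ± 0.26, and the transcription factor Olig1 by 3.19 ± 0.35. Amer2, a regulator of Wnt signalling (1.73 ± 0.19), and Enpep, the aminopeptidase that cleaves angiotensin II (1.33 ± 0.13), also rose. Grin3b, an NMDA receptor subunit, fell by 3.05 ± 0.21, the cyclic GMP phosphodiesterase Pde9a by 2.87 ± 0.28, the carboxylesterase Ces2g by 2.84 ± 0.28, and the calcium-binding protein Caln1 fell by 2.64 ± 0.24. The tight junction protein Tjp3 fell by 2.25 ± 0.20, the terminal complement component C9 by 1.97 ± 0.19, Sel1l3 by 1.81 ± 0.19 and the efflux transporter Abcg2 by 1.44 ± 0.14. Arsg (−1.41), Dtnb (−1.40), the cochaperone Dnajc12 (−1.26) and the inositol trisphosphate kinase Itpka (−1.19) completed the 17 named genes past the test. Each of the 17 lay on the same side in 5 of 5 knockouts because the rule for naming required it. Their adjusted p ran from 0.0200 for Sugct to 0.0495 for Olig1 and Amer2. Another probe of the gene differed by more than 1.5-fold from the one given for Cdhr2 (1.75), Dtnb (−0.65) and Sugct (4.42).

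**Figure D1:**
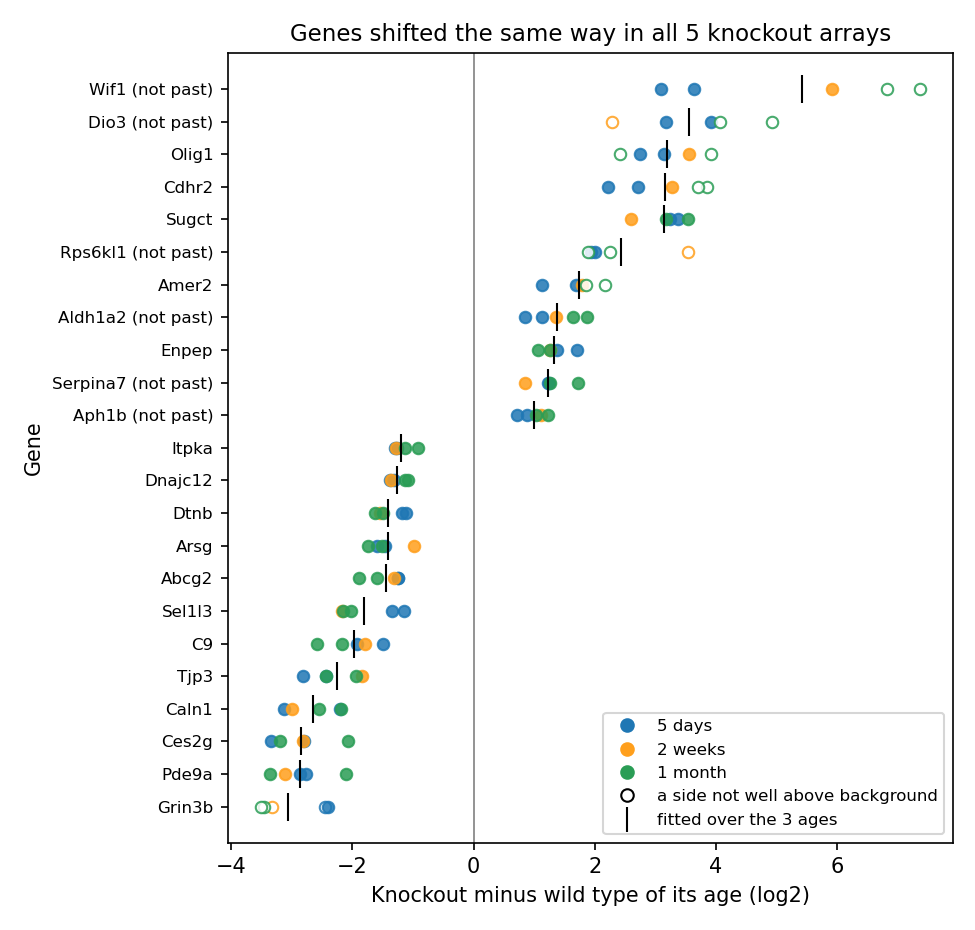
Log2 difference between each knockout array and the wild type of its age (points, coloured by age) and the value fitted over the 3 ages (bars) for 23 named genes, of which those marked as not past had an adjusted p of 0.0509 to 0.0711. All 5 points of each gene lie on the same side of 0 because the rule for naming required it, and open points have a side that was not well above background.

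In all, 25 of 17451 genes passed for knockout against wild type over the 3 ages, 8 higher and 17 lower in the knockouts, and 2514 had an unadjusted p under 0.05 where chance alone would give 872.55. The secreted Wnt inhibitor Wif1 had the largest fitted difference among the named genes, 5.41 ± 0.67, and did not pass (adjusted p = 0.0529). Others just outside were Dio3, the deiodinase that inactivates thyroid hormone (3.55, adjusted p = 0.0509), Rps6kl1 (2.43, 0.0509), the γ-secretase subunit Aph1b (1.00, 0.0509), the retinoic acid enzyme Aldh1a2 (1.37, 0.0565) and the thyroxine carrier Serpina7 (1.22, 0.0711). Where a side was not well above background a bound is given, made from the mean over its arrays of the higher of the array's lowest well-above-background signal and the gene's own. The fitted differences use the signals below that floor and can exceed the bounds. At 1 month the wild type was dim for Olig1 (at least 2.62-fold higher), Cdhr2 (at least 3.52-fold) and Amer2 (at least 4.04-fold), and Grin3b was dim in the knockouts at 2 weeks (at least 7.42-fold lower) and 1 month (at least 7.88-fold lower). The wild type was dim at 2 weeks and 1 month for Dio3 (at least 3.47-fold and 6.30-fold higher) and Rps6kl1 (at least 9.42-fold and 4.19-fold). Slide as a block is set by 5-day knockout replicate 1 alone in the genotype comparisons, so it gives the values obtained without that array and does not otherwise test the slide. The differences were then 3.14 for Sugct (2.99 within slide 1 and 3.36 within slide 2), 3.31 for Cdhr2 (2.99 and 3.78), −3.11 for Grin3b (−2.86 and −3.48) and −2.06 for C9 (−1.85 and −2.38), but 0 genes passed (limma, 2321 at an unadjusted p under 0.05), with the smallest adjusted p at 0.0758. The values within slides 1 and 2 come from different ages and do not test the slide either. The count was 0 without 5-day knockout replicate 2 (2467) or the 1-month wild type (1799), 1 without either 2-week array, 6 and 2 without 1-month knockout replicate 1 and 2, and 39 without genes on X and Y. Flagged local backgrounds distorted the planned normexp background on the 2-week knockout, the 1-month wild type and 1-month knockout replicate 2. With that normexp every call ended (limma), with Olig1 at 1.03, Cdhr2 at 1.23, Grin3b at −0.53 and Sel1l3 at −0.59 (adjusted p = 0.819 for each). Its repaired form gave 151 genes, but Olig1 (1.29), Cdhr2 (1.35) and Amer2 (0.92) lost the call, and median centring gave 60 and trended and robust variance 105.

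Gene lists fixed before the data were examined were tested as sets over the 3 ages, and 8 of 40 passed (3 higher, 5 lower). Of 54 splits of the 8 arrays into groups of the same sizes, 49, the real one included, gave as many lists. Chance could therefore not be excluded for this number. Cell cycle and proliferation genes lay lower, with a median of −0.45 over 51 genes (adjusted p = 1e-07, and adjusted p = 0.904 with an estimated correlation), and examples were Cdk1 (−0.98), Aurka (−0.69), Pcna (−0.37) and Tyms (−0.36). Male-biased and pubertal liver genes had a median of −0.75 over 25 genes (adjusted p = 2.86e-06, and adjusted p = 0.843 with an estimated correlation). Cyp2u1 (−1.95), Nudt7 (−0.75) and the growth hormone receptor Ghr (−0.51) lay lower and the sulfotransferase Sult1c2 lay higher (1.55). Stellate cell and fibrosis genes lay higher, with a median of 0.29 over 43 genes (adjusted p = 1e-07, and adjusted p = 0.843 with an estimated correlation), among them the matrix genes Fbln2 (0.69), Fn1 (0.58) and Col1a1 (0.79) and the ligand Tgfb3 (0.57). Unfolded protein response genes had a median of −0.14 over 29 genes (adjusted p = 0.000154, and adjusted p = 0.843 with an estimated correlation), with Atf6 at −0.36, Trib3 at −1.23, Hyou1 at −0.34 and Creld2 at −0.33. Cholangiocyte and ductular genes had a median of 0.19 over 25 genes (adjusted p = 0.0197, and adjusted p = 0.843 with an estimated correlation), led by the fibrocystin gene Pkhd1 (1.16). Cytochrome P450 and phase I genes had a median of −0.11 over 51 genes (adjusted p = 0.0427, and adjusted p = 0.904 with an estimated correlation), with Aox1 at −1.12, Cyp2c55 at −1.63 and Cyp4v3 at −0.86. Cholesterol biosynthesis genes had a median of −0.10 over 25 genes (adjusted p = 0.0427, and adjusted p = 0.904 with an estimated correlation), with Hmgcs1 at −1.18 (−1.81 to −0.80 over its probes), Sqle at −0.62 and Insig1 at −0.45. Pancreatic acinar genes had a median of 0.93 over 17 genes (adjusted p = 0.0197, and adjusted p = 0.904 with an estimated correlation), with Amy2a5 at 1.36 and Pnliprp1 at 0.96.

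None of the members of these 8 lists passed singly over all genes tested (limma). Adjusted over the list alone, 1 male-biased gene rose and 4 fell, 1 cholangiocyte gene rose, 2 P450 genes fell, and 0 passed in the other lists. At an unadjusted p under 0.05, 12 cell cycle genes were lower and 0 higher, 14 stellate genes higher and 0 lower, 6 unfolded protein response genes lower and 1 higher, 7 cholangiocyte genes higher and 0 lower, 7 cholesterol genes lower and 1 higher, and 2 acinar genes higher and 0 lower. The medians per knockout array differed with age. Cell cycle genes stood at −0.58 and −0.46 at 5 days, 0.23 at 2 weeks and −0.76 and −0.96 at 1 month, and stellate genes at −0.02 and 0.14, 0.49, then 0.47 and 0.35. The acinar median was 2.84 in the 2-week knockout and between −0.07 and 0.13 in the other knockouts, and the 2-week knockout was also the array with the lowest P450 median (−0.70). Without 5-day knockout replicate 1, which is the same as slide as a block, the cholesterol call ended (median −0.06, −0.36 within slide 1 and 0.38 within slide 2). The other 7 lists stayed past, with medians within slides 1 and 2 of −0.09 and −0.94 for cell cycle, 0.33 and 0.41 for stellate, −0.47 and −0.80 for male-biased, −0.12 and −0.30 for unfolded protein response, 0.20 and 0.33 for cholangiocyte, −0.23 and 0.02 for P450 and 1.89 and −0.01 for acinar genes. The values within slide 2 are those of the 1-month comparison, so each pair differs by age and does not test the slide.

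Single arrays moved these medians. Without either 2-week array the cell cycle median was −0.77 and the male-biased median −0.47, the P450 call ended (0.01), the cholesterol call ended (−0.00) and the acinar call ended (0.04). Without the 1-month wild type the medians were −0.20 for cell cycle, −0.37 for male-biased, −0.21 for unfolded protein response, −0.21 for P450 and −0.40 for cholesterol genes. Without the 5-day wild type the stellate median was 0.44 and the P450 median −0.22, and the cholangiocyte (0.28) and cholesterol (0.06) calls ended. The cholesterol median was −0.19 and −0.16 without 1-month knockout replicate 1 and 2, and the cholangiocyte call ended without 5-day knockout replicate 2 (0.19). The number of lists was 14 without either the 5-day or the 1-month wild type. The P450 and cholesterol calls also ended with quantile normalization (−0.10 and −0.08) and with median centring (−0.19 and −0.18), and the stellate (0.03) and cholangiocyte (0.12) calls ended with the planned normexp background.

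**Figure D2:**
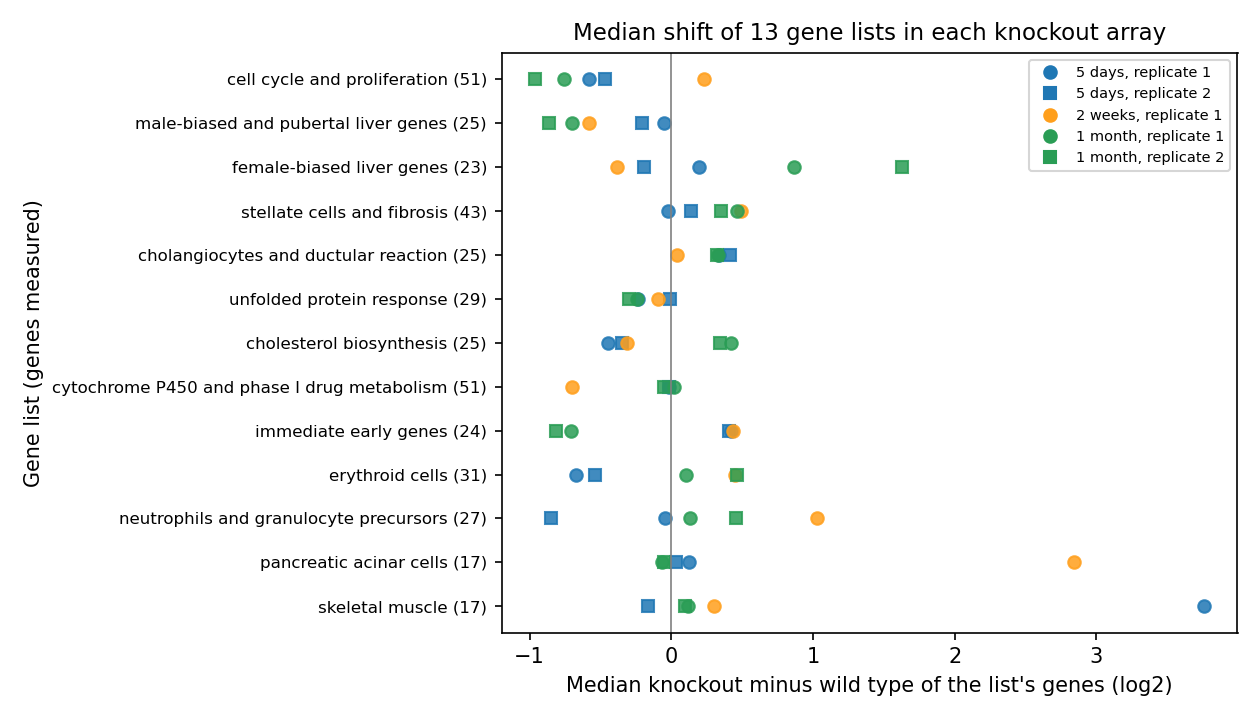
Median log2 difference between each knockout array and the wild type of its age for 13 gene lists, with the number of genes measured in brackets and 1 point per knockout array. Pancreatic acinar genes stand out in the 2-week knockout alone (2.84) and skeletal muscle genes in 5-day knockout replicate 1 alone (3.76).

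At 5 days the comparison asks what differed in the youngest livers, 2 knockouts against 1 wild-type pool. Cell cycle genes had a median of −0.51 (adjusted p = 6.71e-10, and adjusted p = 0.765 with an estimated correlation), erythroid genes of −0.61 over 31 genes (adjusted p = 1.59e-08, and adjusted p = 0.765 with an estimated correlation) and cholesterol genes of −0.40 (adjusted p = 5.95e-05, and adjusted p = 0.765 with an estimated correlation). Immediate early genes had a median of 0.41 over 24 genes and cholangiocyte genes of 0.34 (adjusted p = 0.00608 for each, and adjusted p = 0.765 with an estimated correlation). Neutrophil genes had a median of −0.42 over 27 genes (adjusted p = 0.00961, and adjusted p = 0.916 with an estimated correlation), but stood at −0.04 in replicate 1 and −0.85 in replicate 2. Oxidative phosphorylation genes had a median of −0.12 over 56 genes (adjusted p = 0.0101, and adjusted p = 0.765 with an estimated correlation) and acute phase genes of −0.15 over 45 genes (adjusted p = 0.0126, and adjusted p = 0.867 with an estimated correlation). The fetal transcripts H19 (−0.21), Igf2 (0.13) and Afp (0.05) lay close to wild type, while Wif1 lay 3.36 higher.

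No single gene passed at 5 days (limma, 1774 at an unadjusted p under 0.05). In the 9 lists past the test, 0 members passed over all genes tested, and adjusted over the list alone 1 cholangiocyte gene rose and 1 acute phase gene fell. At an unadjusted p under 0.05, 15 cell cycle, 13 erythroid and 5 cholesterol genes were lower and 0 higher in each. Skeletal muscle genes had a median of 1.87 over 17 genes (adjusted p = 0.00608, and adjusted p = 0.916 with an estimated correlation), which was 3.76 in replicate 1, the array with Xist and without Y-linked signal, and −0.16 in replicate 2. Myoglobin, Mb, read 8.86 in replicate 1 and was not above background in replicate 2 or the wild type, and Cox6a2 read 10.81 against 6.83 and 7.05. Without replicate 1 the muscle median was −0.16 and the neutrophil median −0.85, and the oxidative phosphorylation call ended (−0.10), as it did with quantile normalization (−0.06). Without replicate 2 the muscle median was 3.76 and the neutrophil (−0.04) and immediate early (0.42) calls ended.

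At 2 weeks a single knockout was compared with a single wild type, so that the p-values take their spread from the knockout pairs of the other ages, and the naming of genes at this age was chosen after seeing the data. H19, an imprinted RNA silenced in liver after birth, was 81.4-fold higher (6.35, log2) and its neighbour Igf2, the fetal growth factor, 65.3-fold higher (6.03). The pancreatic enzyme genes Cpa1 (at least 110-fold), Clps (at least 83.9-fold) and Try5 (66.6-fold) were also higher. The major urinary protein genes Mup5 and Mup4 were 45.1-fold and 43.7-fold lower, Trerf1 at least 4.66-fold lower and Grin3b at least 7.42-fold lower. Of 17451 genes, 21 lay past the threshold on that borrowed spread (9 higher, 12 lower), with an adjusted p of 0.032 for these except Trerf1 (0.0419), whose difference was −0.41 as the mean of its probes. With the planned normexp background every call ended (limma), and Trerf1 (1.02) and Grin3b (0.59) turned to the other side. With its repaired form they were lower again (−1.03 and −1.35) without passing. With no replicate on either side these values do not tell the genotype from the animal.

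The acinar list had a median of 2.84 at 2 weeks, with 14 of 17 members at least 2-fold higher, and examples were Cela3b (11.26 against 4.70) and Prss2 (9.29 against 3.59, not above background in the wild type). Gut epithelium and mesothelium genes had a median of 1.03 over 13 genes, neutrophil genes of 1.03, stellate genes of 0.49, erythroid genes of 0.45, P450 genes of −0.70 and male-biased genes of −0.58 in the same array. The calls of single genes at 2 weeks ended without either 5-day knockout or either 1-month knockout (limma). None of these arrays enters the 2-week differences, so only the estimate of spread and its degrees of freedom changed.

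At 1 month the comparison asks what differed in juvenile liver. H19 was 191-fold higher (7.58 ± 0.21, log2, SE, adjusted p = 0.025), Wif1 at least 79.4-fold higher and Igf2 at least 7.55-fold higher. Each was higher in 2 of 2 knockouts, as the rule for naming required. The SEs at this age come from the knockout pairs and hold no spread of the wild type. Hao2, a peroxisomal hydroxyacid oxidase, was 19-fold higher (4.25 ± 0.21), the Rac exchange factor Tiam2 13.9-fold higher (3.80 ± 0.19) and Bex1 at least 3.37-fold higher. Cyp7b1, the oxysterol hydroxylase of the alternative bile acid pathway and a male-biased gene, was 19.7-fold lower (−4.30 ± 0.21), and Grin3b was at least 7.88-fold lower. Of 17451 genes, 12 passed (7 higher, 5 lower), and 2618 had an unadjusted p under 0.05. The balance turned with the scaling. Of 19 genes each with quantile normalization and the deposited matrix 36.84% were higher, of 220 with median centring 40%, and of 145 with repaired normexp 29.66%. The adjusted p was 0.0419 for Wif1, Hao2, Tiam2, Igf2, Cyp7b1 and Grin3b and 0.0464 for Bex1. The planned normexp background was distorted by flagged local backgrounds on the wild type and knockout replicate 2 of this age. With it every call ended (limma adjusted p = 1 for each). The differences were then 4.68 for H19, 3.08 for Hao2, −3.93 for Cyp7b1, 1.90 for Wif1, 0.81 for Tiam2, −0.81 for Grin3b and 0.33 for Igf2, and Bex1 turned to −0.07. With its repaired form Bex1 lost the call (0.80).

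At this age 10 lists passed. Cell cycle genes had a median of −0.94 (adjusted p = 2.01e-16, and adjusted p = 0.578 with an estimated correlation), with 0 of 51 past over all genes tested, 28 fallen and 1 risen adjusted over the list alone, and Cdk1 at −1.81 and Aurka at −1.24. Male-biased genes had a median of −0.80 (adjusted p = 1.04e-11, and adjusted p = 0.488 with an estimated correlation), with Cyp7b1 past over all genes and 12 fallen and 1 risen adjusted over the list alone, among them Cyp2u1 (−2.64), Nudt7 (−1.05) and, on the other side, Sult1c2 (2.41). Female-biased genes had a median of 1.37 over 23 genes (adjusted p = 0.00141, and adjusted p = 0.578 with an estimated correlation), with Hao2 past over all genes and 7 risen adjusted over the list alone, and the median was 0.86 without replicate 2 and −0.05 with the planned normexp background. Immediate early genes had a median of −0.84 (adjusted p = 2.85e-09, and adjusted p = 0.488 with an estimated correlation), with 5 fallen adjusted over the list alone, among them the transcription factor Maff (−3.24). Genes of the urea cycle and amino acid catabolism had a median of 0.39 over 41 genes (adjusted p = 6.84e-06, and adjusted p = 0.488 with an estimated correlation), with 3 risen adjusted over the list alone. Fatty acid synthesis genes had a median of 0.38 over 29 genes (adjusted p = 0.00539, and adjusted p = 0.578 with an estimated correlation), with 7 risen and 1 fallen. Oxidative phosphorylation (0.34, adjusted p = 3.2e-07), stellate (0.41, 2.74e-05), unfolded protein response (−0.30, 5.33e-05) and interferon genes (0.41, 0.000954) had 0 members past on either count (limma), and 5, 8, 3 and 12 members at an unadjusted p under 0.05. For these 4 lists the estimated correlation gave an adjusted p = 0.578, or 0.622 for interferon genes. Fetal and oncofetal genes did not pass as a list (median 0.16 over 24 genes), although H19 and Igf2 rose. The calls of single genes at 1 month ended without either 5-day knockout or either 1-month knockout (limma). Leaving out a 5-day knockout does not change the 1-month differences, only the estimate of spread and its degrees of freedom.

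Chosen after seeing the data, the mean effect over 2 weeks and 1 month was taken because the Arid1a probe was lower at these ages. H19 rose by 6.96 ± 0.16 (adjusted p = 0.0129), Igf2 by 4.85 ± 0.12 (0.0129) and Wif1 by 6.5 ± 0.27 (0.0272), with the 1-month wild type dim for Igf2 and Wif1. The SEs and p-values of this comparison take their spread from the knockout pairs at 5 days and 1 month. They hold no spread of the wild types or the 2-week knockout, and no difference between the later ages. Afp, the fetal serum protein silenced after birth, rose by 2.17 ± 0.13 (0.0313), was higher in 3 of 3 knockouts and was singled out after its value was seen. With the planned normexp background every call of this comparison ended, with H19 at 4.60, Igf2 at 1.99, Wif1 at 2.66 and Afp at 0.93. In wild type H19 went from 16.97 at 5 days to 10.12 and 5.63 at the later ages, in the knockouts from 16.67 and 16.84 to 16.46 and then 13.37 and 13.04. Also higher were Sugct (2.98), Hao2 (2.6), Syngr1 (2.33), the water channel Aqp4 (2.30) and the chemokine Cxcl1 (2.21). With the wild type dim, Cpa1 was at least 110-fold higher at 2 weeks (and dim in both genotypes at 1 month), Cdhr2 at least 3.52-fold and Bex1 at least 3.37-fold at 1 month, and Rps6kl1 at least 9.42-fold and 4.19-fold at the 2 ages. Lower were Mup5 (−3.15), Cyp7b1 (−2.96), Mup4 (−2.80), Smim22 (−2.67), the odorant receptor gene Olfr1215 (−2.66), Cabyr (−2.40), the desmoglein Dsg1c (−2.30) and Sel1l3 (−2.13). The Mup values came mostly from the 2-week pair, with Mup5 at −0.80, Mup4 at −0.16 and Mup9 at −1.82 at 1 month. With the planned normexp background little was left of Sel1l3 (−0.32), Sntg2 (−0.25), Dsg1c (−0.21), Grin3b (−0.11) and Cabyr (−0.05), and Cd276 turned to 0.70. With its repaired form these kept their call except Cd276 (−0.34), and Cdhr2 (1.19) lost it. With the knockout dim, Mup9 was at least 19.6-fold and Sntg2 at least 8.78-fold lower at 2 weeks, Grin3b at least 7.42-fold and 7.88-fold and the immune ligand Cd276 at least 1.12-fold and 1.76-fold lower at 2 weeks and 1 month.

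**Figure D3:**
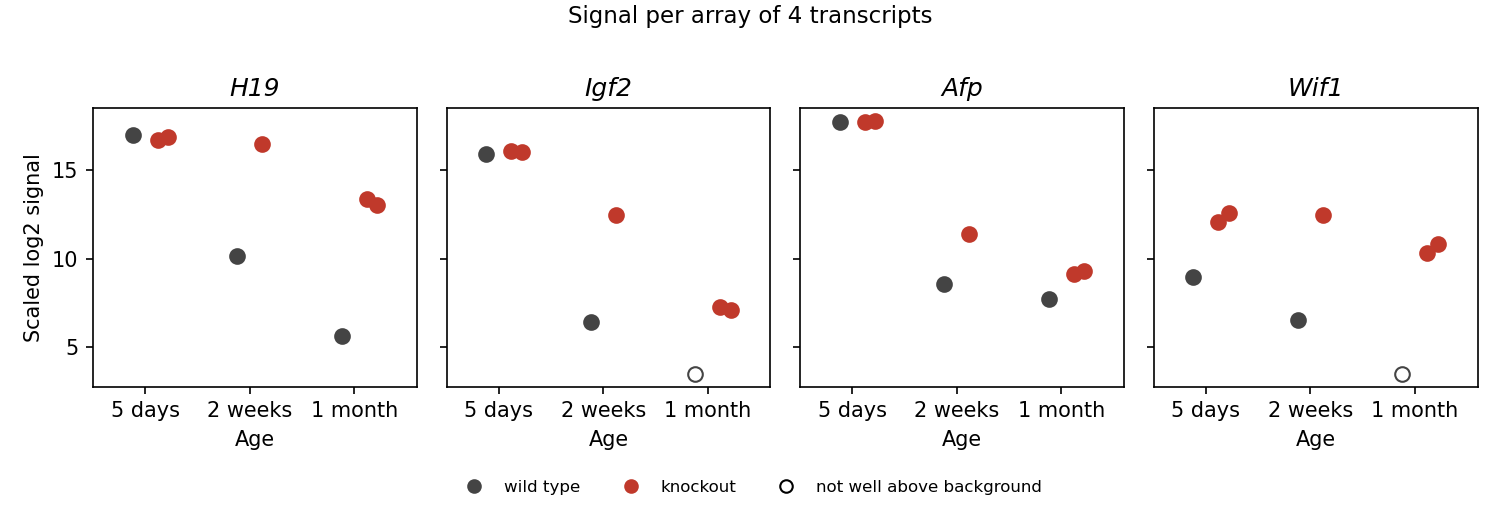
Scaled log2 signal of H19, Igf2, Afp and Wif1 on each array by age, wild type in grey and knockout in red, with open points for signals not well above background. The later knockouts lie above the wild type of their age in each panel, and for Wif1 the 5-day knockouts (12.05 and 12.59) also lie above the wild type (8.96).

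In this added comparison 73 genes passed, 34 higher and 39 lower, and 2912 had an unadjusted p under 0.05. Median centring gave 282 genes, 39.72% of them higher, and repaired normexp 255, 32.16% of them higher. Of 12 lists past the test (7 higher, 5 lower, adjusted p = 0.613 to 0.617 with an estimated correlation), male-biased genes had a median of −0.93 with 3 of 25 fallen, and 17 fallen and 1 risen adjusted over the list alone. Acinar genes had a median of 1.36, carried by the 2-week knockout alone, with 4 past the test (12 adjusted over the list alone), and fetal genes of 0.29 with H19, Igf2 and Afp risen (5 risen and 2 fallen adjusted over the list alone). Pericentral genes had a median of −0.36 with 11 fallen and 4 risen adjusted over the list alone, carried by the 2-week knockout (−0.64, against −0.03 and −0.14 in the 1-month knockouts). Erythroid genes had a median of 0.57 with 13 risen and 2 fallen, which was 0.35 without 1-month knockout replicate 2. Their call ended with all arrays above background (−0.02, adjusted p = 0.734) and with repaired normexp (0.16, adjusted p = 0.111). Stellate (0.45), interferon (0.33), neutrophil (0.64), oxidative phosphorylation (0.16), cell cycle (−0.33) and unfolded protein response genes (−0.17) had 0 members past on either count (limma, with 22, 9, 6, 2, 12 and 5 members at an unadjusted p under 0.05), and P450 genes (−0.20) had 5 fallen and 2 risen adjusted over the list alone. P450 genes were also carried by the 2-week knockout (−0.70, against 0.02 and −0.05 in the 1-month knockouts). Cell cycle genes lay on opposite sides at 2 weeks (0.23) and 1 month (−0.76 and −0.96), oxidative phosphorylation genes were higher at 1 month alone (0.01, then 0.31 and 0.34), and neutrophil genes stood at 1.03, then 0.13 and 0.46. The calls of single genes over 2 weeks and 1 month ended without any 1 of the 4 paired knockouts (limma). Leaving out a 5-day knockout does not change these differences, only the estimate of spread and its degrees of freedom. With the planned normexp background the stellate (−0.04), interferon (−0.07), fetal (0.05), cell cycle (−0.11) and erythroid (0.54) calls ended and the oxidative phosphorylation median turned to −0.71.

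Whether the knockout effect itself differed between 1 month and 5 days was tested directly. H19 had the difference 7.79 (adjusted p = 0.0775) and Igf2 3.53 (adjusted p = 0.203), and 0 of 17451 genes passed (limma, 1842 at an unadjusted p under 0.05). The effect over the later ages minus that at 5 days also gave 0 genes (limma, 1769). Across genes, which are not independent replicates, the knockout effects had a Spearman rho of 0.148 between 5 days and 2 weeks, 0.201 between 5 days and 1 month and 0.294 between 2 weeks and 1 month, 3 relations in all (Pearson r 0.225, 0.184 and 0.308). The rho between 2 weeks and 1 month turned negative with the planned normexp background, which was distorted on arrays of both ages. It was smaller without a filter. That between 5 days and 2 weeks was smaller with some single arrays left out.

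The genes 2-fold or more on the same side in all 5 knockouts numbered 61, 19 higher and 42 lower, against a mean of 3.92 and at most 9 in 100 simulations of independent normal noise with each gene's residual spread. That noise holds no structure shared between arrays, such as the slide, so the simulations do not exclude one as a source of the number. Sugct, Wif1, Grin3b and C9 were among them. The number was 252 without the 5-day wild type and so without that age, and 137 without the 1-month wild type. Both of these ask for fewer knockouts. It fell to 9 with the planned normexp background, and was also smaller with its repaired form and with all arrays above background. For some of the 61 a side was dim, so that 2-fold was not measured there. Cacna1d was at least 1.13-fold, 1.37-fold and 1.30-fold higher at 5 days, 2 weeks and 1 month. Tmed6 was at least 1.62-fold, 1.96-fold and 1.93-fold lower. Others, such as Sugct and C9, were above background on every array.

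The last comparisons ask how liver changed with age. Over both genotypes, 9941 of 17451 genes differed between 1 month and 5 days, 5282 higher and 4659 lower. The share higher was 48.69% with quantile normalization, 48.61% with the deposited matrix, 63.32% with median centring and 63.21% with repaired normexp. The planned normexp background gave 405 genes, 33.09% of them higher. Mup4 (12.83 ± 1.02, log2, SE) and Mup3 (12.32 ± 0.76) rose, and with dim arrays at their floor Mup1 was at least 21633-fold, Mup5 at least 10583-fold, Mup8 at least 4239-fold and the acute phase gene Orm2 at least 937-fold higher. Cstdc5, one of the stefin genes of granulocyte precursors, fell by 10.10 ± 0.60, and Stfa1 (at least 1415-fold), Csta1 (at least 1250-fold), Igf2 (at least 891-fold), Stfa2l1 (at least 362-fold) and Cstdc4 (at least 324-fold) were lower at 1 month. The count for 1 month against 5 days over both genotypes was 6319 with slide, which is partly confounded with age, as a block. The median of all genes in this comparison was 0.0914, and 0.253 with median centring, so changes of that size depend on the scaling.

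In the knockouts alone, 8120 genes differed between 1 month and 5 days, 4124 higher and 3996 lower. The share higher was 46.46% with quantile normalization, 46.59% with the deposited matrix, 61.59% with median centring and 63.27% with repaired normexp. The planned normexp background gave 125 genes, 55.2% of them higher. Of the cell cycle list 48 of 51 genes fell (median −2.92, Cdk1 −3.86 and Aurka −2.92), and of the fetal list 19 of 24 fell and 1 rose (median −2.85, Igf2 −8.87, H19 −3.55 and Spink1 −2.34). Neutrophil genes fell in 23 of 27 cases (−4.20), erythroid genes in 22 of 31 with 2 risen (−2.24), stellate genes in 33 of 43 with 2 risen (−1.38) and lymphocyte genes in 27 of 37 with 2 risen (−1.71). Oxidative phosphorylation genes rose in 54 of 56 cases (1.05), P450 genes in 40 of 51 (1.63, Aox1 3.10), phase II genes in 31 of 36 with 1 fallen (1.71, Gstm2 3.4), urea cycle genes in 35 of 41 with 1 fallen (1.76) and male-biased genes in 21 of 25 with 2 fallen (2.25). In all, 27 of 40 lists passed, 17 higher and 10 lower, and 0 with an estimated correlation, where these lists had an adjusted p = 0.223 to 0.495. The gene count for 1 month against 5 days in knockouts was 5223 and 4752 without 1-month knockout replicate 1 and 2. The median of all genes was 0.0938, and 0.264 with median centring.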

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

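The tests in this part were chosen before the data were examined, except the repaired form of the normexp background, which was added after its planned form was seen. The knockout effect at 1 month minus that at 5 days was tested for each of 40 gene lists, and 19 lists differed between the ages by camera at the preset correlation. With an estimated correlation all 19 calls were lost (camera adjusted p = 0.509 to 0.691). That test has few degrees of freedom and passed no list in any comparison, so this loss cannot decide. Each age had 1 wild-type array, and 5 days and 1 month lay mostly on different slides. In single genes 0 of 17451 differed (limma, 1842 at an unadjusted p under 0.05), and the effects of slide, age and the mixed sexes at 5 days were not separated. No explanation is offered for these differences.

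The lists whose knockout effect was lower at 1 month than at 5 days were immediate early genes (median difference −1.204), male-biased and pubertal liver genes (−0.9123), cell cycle genes (−0.4231), gut epithelium and mesothelium genes (−0.4789), skeletal muscle genes (−2.001) and p53 targets (−0.1686). The muscle value rests on 5-day knockout replicate 1, without which (the same, for the genotype, as slide as a block) it was 0.05, and it was −4.57 without replicate 2. The cell cycle difference was 0.07 and the lymphocyte difference −0.20 with the planned normexp background, and with its repaired form they were −0.04 and 0.21 and both calls ended. The cell cycle difference was −0.26 as the mean of probes, and the muscle difference −0.97 with all arrays above background.

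The lists whose effect was higher at 1 month, among metabolic genes, were oxidative phosphorylation (0.4049), urea cycle and amino acid catabolism (0.4445), cholesterol biosynthesis (0.6177), fatty acid and triglyceride synthesis (0.6374), phase II conjugation (0.3999), gluconeogenesis and glycogen (0.4188) and female-biased liver genes (1.533). Among blood, inflammatory and other cell types they were erythroid cells (0.9111), interferon response (0.6079), acute phase and IL-6/STAT3 targets (0.628), stellate cells (0.3188), neutrophils (0.7813) and lymphocytes (0.5791). Without 5-day knockout replicate 2 the neutrophil (0.40) and lymphocyte (0.31) calls ended, as did those of gut (−0.45), p53 (−0.23) and phase II genes (0.29), and the interferon difference was 0.40. Without 5-day knockout replicate 1 the gluconeogenesis (0.31) and stellate (0.29) calls ended, the neutrophil difference was 1.22 and the p53 difference −0.11. Without 1-month knockout replicate 1 the gluconeogenesis (0.34) and stellate (0.26) calls ended, the gut difference was −0.76 and the p53 difference −0.04, and without replicate 2 the acute phase call ended (0.35).

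The planned normexp background gave smaller differences for female-biased (0.14), erythroid (0.26), interferon (0.28), acute phase (0.30), fatty acid synthesis (0.42) and neutrophil genes (0.03), and the stellate (0.00) and gut (−0.50) calls ended. With its repaired form the differences were 0.83 for female-biased, 0.56 for erythroid and 0.46 for neutrophil genes, and the stellate (0.17), gut (−0.36) and gluconeogenesis (0.37) calls ended. With all arrays above background the erythroid difference was 0.36 and the neutrophil (0.72) and gut (−0.48) calls ended. The oxidative phosphorylation difference was 0.24 with quantile normalization and with the deposited matrix, and the gluconeogenesis call ended with these (0.32 and 0.33) and with median centring (0.44).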

How the results depend on the processing

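Tests chosen after seeing the data were normexp with repaired backgrounds, the fits without the 5-day arrays or without genes on X and Y, and all comparisons over the 2 later ages. The cause was not tested where none is named. Of 354 values of counts, correlations and the Arid1a difference under the alternatives, 265 stayed, 88 moved and 1 turned. Of 1522 values of named genes past the test, 972 kept their call, 546 lost it and 4 turned. Of 1300 values of named genes not past, 1222 stayed, 73 passed and 5 turned. Of 1085 values of lists, 1004 kept their call, 72 lost it and 9 turned. List members were followed only where named in the text. These tallies overstate the number of separate alternatives. In the fit with 6 groups a group's lone array leaves no residual, so leaving it out changes nothing in comparisons without it. Over the 3 ages, leaving out either 2-week array equals leaving out the pair. For the genotype, slide as a block repeats the fit without 5-day knockout replicate 1. The deposited matrix nearly repeats quantile normalization. Counts of 0 genes here are from limma, with 40 to 3087 genes (the latter for knockout against wild type over 2 weeks and 1 month) at an unadjusted p under 0.05. Arid1a stayed lower throughout (−0.56 to −0.33 over single arrays left out). H19 at 1 month ranged from 4.68 to 7.74 with its adjusted p from 0.00163 to 1, and Sugct over the 3 ages from 1.55 to 3.78 with its adjusted p from 0.00416 to 0.819. A change in a correlation counted as moved over 0.1, a margin set after seeing the data. A count of genes or lists stayed when it was within 1.5-fold of the count with the values used. A count of 0 in both also stayed.

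With the planned normexp background, genes passing were 0 over the 3 ages, 405 for age over both genotypes, 125 for age in knockouts, and 0 at 2 weeks, at 1 month and over the later ages. The 2-fold rule gave 9 genes, lists were 26 over the 3 ages, 21 at 1 month and 28 over the later ages, and the correlation of effects at 2 weeks and 1 month was −0.555. It turned Trerf1 (1.02) and Grin3b (0.59) at 2 weeks, Bex1 at 1 month (−0.0718), Cd276 over the later ages (0.70), the cell cycle (0.0688) and lymphocyte (−0.20) lists between 1 month and 5 days, and the stellate (−0.0441) and oxidative phosphorylation (−0.71) lists over the later ages. For lists, a turn is a change in the direction of the test. The medians of interferon genes over the later ages (−0.0659) and of female-biased genes at 1 month (−0.0539) also fell below 0. Local backgrounds of up to 62854 that carried an outlier flag lifted the 5th percentile of the 2-week knockout, the 1-month wild type and 1-month knockout replicate 2 to 10.1, 8.29 and 9.79, and 6.00, 5.93 and 6.12 after repair. Repaired, genes were 151 over the 3 ages, 38 at 2 weeks, 145 at 1 month, 255 over the later ages, 2 for each difference from 5 days, and 26 by the 2-fold rule. As planned the median of all genes was 0.244 at 2 weeks and −0.114 at 1 month, against 0.0149 and 0.0487 with the values used.

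Quantile normalization and the deposited matrix each gave 1 gene at 5 days and 19 at 1 month. Median centring gave 60 over the 3 ages, 4 at 5 days, 69 at 2 weeks, 220 at 1 month, 282 over the later ages and 2 for each difference from 5 days. Without a filter genes were 3 over the 3 ages, 47 at 2 weeks and 26 at 1 month, lists at 1 month 16 and the correlation of 2 weeks and 1 month 0.165. With all 8 arrays above background, which tests fewer genes, they were 79 over the 3 ages, 6 at 2 weeks, 60 at 1 month, 1 for each difference from 5 days and 30 by the 2-fold rule. The mean of probes gave 58 over the 3 ages. For the genotype, slide as a block equals leaving out 5-day knockout replicate 1, the only array that informs it, and does not otherwise test the slide. It gave 0 over the 3 ages, at 2 weeks, at 1 month and over the later ages, 6319 for 1 month against 5 days over both genotypes, and −0.16 for muscle genes at 5 days. Trended and robust variance gave 105 genes for knockout against wild type over the 3 ages, 9 at 5 days, 40 at 2 weeks, 124 for knockout against wild type at 1 month, 222 for knockout against wild type over 2 weeks and 1 month, and 4 and 2 for the differences of 1 month and of the later ages from 5 days. Without the 2-week pair 1 gene passed over the 3 ages and the acinar median was 0.0381. Without the 5-day arrays counts were 3 over the 3 ages, 0 at 2 weeks, at 1 month and over the later ages and 252 by the 2-fold rule, which then needs 3 knockouts. Without genes on X and Y 39 passed over the 3 ages. A 1.5-fold rule gave 193 genes. Lists over the 3 ages were 0 with an estimated correlation and 0 with fry, and over the later ages 0 with an estimated correlation. The value for Arid1b: knockout against wild type over the 3 ages turned to 0.0260 with quantile normalization, 0.0255 with the matrix, 0.0173 with repaired normexp, 0.0867 without the 1-month wild type and 0.02 without 1-month knockout replicate 2.

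Leaving out each array in turn gave 0 to 23 genes over the 3 ages, 0 to 0 at 5 days, 0 to 21 at 2 weeks, 0 to 12 at 1 month, 0 to 73 over the later ages, 0 to 0 for both differences from 5 days, 8305 to 9675 for 1 month against 5 days over both genotypes, 4752 to 8120 for 1 month against 5 days in knockouts and 68 to 252 by the 2-fold rule. Lists ranged from 6 to 14 over the 3 ages, 8 to 11 at 5 days, 10 to 13 at 1 month, 14 to 19 between 1 month and 5 days and 12 to 15 over the later ages, and the correlations from 0.0646 to 0.195 (5 days and 2 weeks), 0.154 to 0.229 (5 days and 1 month) and 0.242 to 0.309 (2 weeks and 1 month). Muscle genes at 5 days ranged from −0.16 (without knockout replicate 1) to 3.76, acinar genes over the 3 ages from 0.0381 (without either 2-week array) to 1.31 and the value for Arid1b: knockout against wild type over the 3 ages from −0.0838 to 0.0867. With the replicate block, age in knockouts gave 6635 genes. Fitted differences of genes with a dim side rest on signals near background.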

Other observations

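Tests chosen only after their result was seen were that of slower maturation and that of the sex of the 5-day mice, and the comparison over the 2 later ages was also added then. Other gene groups did not pass as lists over the 3 ages but held single members past the test adjusted over the list alone. Of the acute phase list (45 genes), the hepcidin gene Hamp2 (−3.57) and the orosomucoids Orm1 (−2.92) and Orm2 (−2.84), which were dim in the 5-day knockouts, fell (adjusted p = 0.0134 over the list alone) and Serpina3n rose (1.30, adjusted p = 0.0314 over the list alone). Over all genes tested these did not pass (adjusted p = 0.0755, 0.0979, 0.0831 and 0.135). Of the complement and coagulation list (39 genes), C9 fell by 1.97 over all genes tested and C4b fell by 2.50 over the list alone (adjusted p = 0.0396). Of 36 phase II genes 4 rose and 5 fell adjusted over the list alone, among them the glutathione transferase Gstm2 (0.73) and the glucuronosyltransferase Ugt2b35 (−0.69), and Gstm2 stood at 0.82 at 1 month. In the fetal and oncofetal list (24 genes, median 0.24) the trypsin inhibitor Spink1 fell adjusted over the list alone (−2.35), on the opposite side to H19 and Igf2. In the erythroid list (31 genes) the carbonic anhydrases Car1 (−0.89) and Car2 (−0.76) fell adjusted over the list alone. The BAF complex list (28 genes) had a median of 0.01 with 0 members past on either count (limma, 4 at an unadjusted p under 0.05), and its members of smallest p after Arid1a included Smarca2 (−0.47) and Smarce1 (−0.26). Hepatocyte identity (0.09) and ribosomal protein genes (−0.02) had 0 members past (limma, 6 and 0 at an unadjusted p under 0.05). The 32 lists that did not pass over the 3 ages had medians from −0.64 (adipose tissue, 8 genes, 1 risen and 5 fallen adjusted over the list alone) to 0.79 (skeletal muscle, 17 genes).

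H19, Igf2 and Afp were higher in the knockouts at 2 weeks and 1 month. Had 5-day liver RNA been mixed into the later knockout samples, the share needed for H19 (70.2%, 8.23% and 6.54% in the 3 arrays) would match the share needed for Afp (1.09%, 0.169% and 0.205%), but it was at least 31.93 times as large, which argues against that source for H19. For Igf2 the shares were 8.98%, 0.229% and 0.204%, close to those for Afp at 1 month, so at that age such a mixture stays open for Igf2 and Afp. Under the other 4 normalizations the H19 difference at 1 month was at least 4.679 (log2), which argues against the scaling as the cause for H19. For Igf2 at 1 month and Afp over the later ages the differences were 0.33 and 0.93 with the planned normexp background, which flagged local backgrounds distorted. With its repaired form, added after seeing the data, they were 1.32 and 1.92. These values bear on the background correction more than on the scaling, so for Igf2 and Afp the scaling stays open. Slower postnatal maturation across the transcriptome may contribute: knockout minus wild type and wild type at 5 days minus wild type of the other later age had a Pearson r across genes of 0.329 at 2 weeks but 0.09357 at 1 month, between the bounds set for and against it, so it stays open. A direct effect on these genes was not tested.

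Pancreatic acinar transcripts were higher in the 2-week knockout alone. Pancreas carried over with the liver piece could account for this, since 82.35% of the 17 measured acinar genes (14) were at least 2-fold higher. Marker levels had a Spearman rho across genes of 0.308 to 0.694 with the other knockouts, not over the 0.7 that was asked for. Those knockouts had acinar medians of −0.07 to 0.13, so their marker levels need not follow pancreas, and this rho cannot decide. With 1 array per genotype, carried-over pancreas cannot be told apart from a change in that animal. Gut epithelium and mesothelium genes, another list of tissue that can be carried over, had a median of 1.03 in the same array. A general shift of these genes with the knockout is argued against by the other knockouts, whose lowest median was −0.06516.

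Genes at least 2-fold on the same side in 5 of 5 knockouts numbered 61, although 5-day mice of both sexes were among them. For some of these genes a side was not well above background, and the number was lower with both forms of the normexp background. A chromosome segment linked to Arid1a of another strain origin might have given such a set, but 1 of its 60 mapped genes lay within 20 Mb of the Arid1a probe where 1.82 were expected (Fisher's exact test, one-sided, p = 0.843). Segments elsewhere, also farther along chromosome 4, were not tested. Some of the 61 lay close together, such as C4a and C4b on chromosome 17 and Orm1 and Orm2 on chromosome 4. Enho, Plppr1, Ube2u and Ttc39a also lay on chromosome 4 outside that window. For the sex of the 5-day mice, of 252 genes 2-fold on one side in the 3 later knockouts, 67.06% had both 5-day knockouts, one with a female and one with a male pattern, on that side, 18.25% had them on opposite sides and 14.68% both on the other side. The 61 genes lie within the 252 and were selected for that outcome, and in the 191 others the shares were 56.54%, 24.08% and 19.37%, where unchanged arrays that share 1 wild type would give 33.33% each. All 5 later arrays had a male pattern, so the 61 genes were 2-fold on one side in 3 knockouts compared with male-pattern wild types and in 5-day knockouts of both patterns, which argues against sex as their cause. The genotype was not tested apart from slide and animal.

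For the 25 genes past the test for knockout against wild type over the 3 ages, 3 of the 54 splits of the 8 arrays that could be fitted, the real one included, gave as many, so chance could not be excluded, and the highest other split gave 96. That split set 5-day knockout replicate 1 against the other 5-day arrays, which follows both the slide and the array with Xist and muscle signal, and so points to a structure of the samples. The third split, with 28 genes, equals the comparison of genotypes at 1 month. Without 5-day knockout replicate 1, to which slide as a block amounts here, the real count was 0 (limma, 2321 at an unadjusted p under 0.05). For the 8 lists, 49 of 54 splits, the real one included, gave as many and the highest other gave 18, so chance could not be excluded. For age, 1 of 10 splits of the 6 arrays of 5 days and 1 month, the real one, gave as many as its 9675 genes, and the highest other gave 7. These splits are too few for a share under 0.05.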
